A study of Mus musculus with 2 samples.

How the data were processed

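Total liver RNA of mouse was measured in 2 samples, 1 array each. The deposited values are single-colour signal intensity on a linear scale, 1 value per Affymetrix probe set and array; all are above 0. The mean after trimming 2% of probe sets at each end was 500.5 on both arrays, as global scaling to a common target would give, but the scaling step, the summary method, the software and detection calls are not given in the sources used here. Scanner files were not used here. Because only summarised intensities were at hand, background correction and normalization could not be repeated, and they can change low signals in particular. All columns of the table were used.

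Of the 12488 probe sets, 66 are array controls. The platform annotation supplied with the table named 1 gene for 10855 probe sets, several genes for 396 and no gene for 1237. Symbols were looked up by gene identifier in a RefSeq table of assembly GRCm38.p6, where 10839 of the 10855 matched and 0 symbols changed. No coordinates are given because the array's annotation names no genome build. Probe sets with several genes or none stayed out of the gene lists. The 10833 named non-control probe sets covered 8251 genes, of which 2073 had more than 1 probe set. A gene was represented by its probe set with the highest mean log2 signal over both arrays.

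Both samples form 1 group, named from their titles; the source field names spleen, and gene levels were used to describe this conflict and not to assign samples. The arrays were not copies of one another: 16 of the 12488 values were identical. With a single group there was no test between groups and no p-value was computed. Before the data were examined, 29 gene lists, the alternatives and the rule for named genes were fixed. For each list the median percentile of its genes among all genes of the array was computed, and placed among the medians of 10000 random lists of the same size (seed 1). These random lists were matched on the number of probe sets per gene, with genes of 3 or more sets pooled. A background threshold was the 95th percentile of 94 genes of brain, testis, retina and striated muscle. Agreement used the brighter 50% of non-control probe sets by mean log2 signal, after subtracting the median difference; 95% intervals of correlations came from 1000 bootstrap samples of probe sets. List differences used genes in the brighter 50%, lists of at least 5 such genes, and random lists matched in 20 signal bins. The middle 95% runs from the 2.5th to the 97.5th percentile of random lists. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

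The named genes are the 3 highest and the lowest of each list by mean percentile, the 10 brightest, the 5 most different in each direction among the brighter 50%, and 16 fixed genes, of which 5 were not analysed here. Exceptions are stated where they occur. Alternatives were quantile normalization, no shift, all probe sets, the brightest 25%, log2(value + 32), leaving out probe sets of suffix f, s, r, i or g, the mean of a gene's probe sets, unmatched random lists, other background thresholds, and each array alone. The steps were tested on simulated data. Of 100 simulated lists of 20 genes shifted by a log2 of 0.3 between the arrays, 100 fell outside the random range, and of 100 unshifted lists 4 did (4126 genes). For list positions, 100 of 100 lists drawn from the brightest 25% and 7 of 100 drawn from all genes fell outside (8251 genes). In a simulated array pair, the 2-fold limit caught 2 of 50 genes changed by a log2 of 0.58, 22 of 50 changed by 1, 50 of 50 changed by 2, 50 of 50 changed by 3, and 15 of 3926 unchanged genes. The simulated noise was normal, with a spread from the median deviation at each signal, which gives little weight to extreme differences. On the real arrays 2.09% of the brighter probe sets passed 2-fold, so the simulated counts are not error rates for these data. The lists that lay outside their range on the real arrays held 6, 9, 14 and 17 genes, and lists of those sizes were not simulated.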

Results

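Mouse liver RNA was profiled on 2 single-colour oligonucleotide arrays. Both samples were titled liver and were described as total RNA of the same catalogue item from a commercial supplier, while their source field named spleen. The group used here was taken from the titles. The labels define 1 group and no treatment, so the design implies a description of the liver profile, a check of the tissue label and a comparison of the 2 arrays with each other. No statement about lots or animals was found in the labels, so the spread between the arrays may be purely technical, and it describes these 2 arrays alone. Each array carried 12488 probe sets. The median signal was 163.2 on replicate 1 and 157.7 on replicate 2, and the highest signal was 64627 and 72959. The mean signal after trimming 2% of the probe sets at each end was 500.5 on both arrays. Arrays give no count depth, and having only 2 of them limits the precision of every value.

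The control probe sets of the array were examined on both arrays. The 9 probe sets named at for the biotin-pathway and cre hybridization controls lay between 428.5 and 35720, and the sets named st for the same controls between 17.0 and 520.9. The 19 probe sets for Bacillus and yeast sequences reached at most 99. The control probe sets for Gapdh, a glycolytic enzyme, gave 25066 and 24148 at the 3′ end and 25633 and 25317 at the 5′ end on replicates 1 and 2. Those for beta-actin gave 14576 and 15169 at the 3′ end and 9249 and 10344 at the 5′ end. The at sets of both genes differed between arrays by at most a factor of 1.12, whereas some of their st sets, none above background on both arrays, differed more, such as the 5′ st set of Gapdh (251.1 and 34.7). The sets for pyruvate carboxylase gave 5217 and 5430 at the 3′ end and 1164 and 1125 at the 5′ end. Those for 18S ribosomal RNA, none above background on both arrays, differed between arrays by up to 2.64-fold. These control probe sets were chosen after their values were seen.

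The first question was which genes were bright in this RNA. The 10 brightest genes were Apoe, Serpina1c, Alb, Apoa1, Serpina1b, Serpina1e, Cyp2e1, Mup3, Hp and Rpl41. Of these, 8 encode proteins the liver secretes: apolipoproteins E and A1, albumin, 3 alpha-1-antitrypsin genes, a major urinary protein and the haemoglobin scavenger haptoglobin. Cyp2e1 is an ethanol-oxidising cytochrome P450, and Rpl41 is a ribosomal protein. Apoe had a signal of 67766 ± 7343 (SD, n = 2 arrays), Alb 65213 ± 829.6, Apoa1 65054 ± 6337, Cyp2e1 49701 ± 5023 and Hp 43648 ± 3553. The Serpina1 genes and Mup3 have near-identical copies, and probe sets cannot assign their signal to 1 copy. Probe brightness depends on probe sequence, so these values place genes within the array's signal and do not rank transcript abundance.

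A background was set from genes of tissues other than liver and spleen. It used 94 genes of brain, testis, retina and striated muscle, and its 95th percentile fell at a signal of 386.8 on replicate 1 and 373.3 on replicate 2. Of the 8251 named genes, 2845 (34.5%) lay above it on both arrays. The brain genes had a median percentile of 21.0 and the testis, retina and muscle genes one of 31.9, and 5 of the 94 exceeded the threshold on both arrays. Among these, Tnp1, a transition protein of spermatids, gave 1104 ± 85.8 and Acta1, skeletal muscle actin, gave 739.8 ± 89.8. Of the 5, Tnp1, Pcp2 and Crybb2 were read from probe sets of suffix r, and Oxt and Acta1 from plain ones. On replicates 1 and 2 the other set of Tnp1 gave 8.7 and 8.2, that of Pcp2 147.8 and 173.3, and that of Crybb2 15.9 and 11.3. Of the ribosomal protein genes 7 of 25 and of the oxidative phosphorylation genes 7 of 26 were not above the threshold on both arrays. A gene below it is described as not above background, not as absent.

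**Figure D1:**
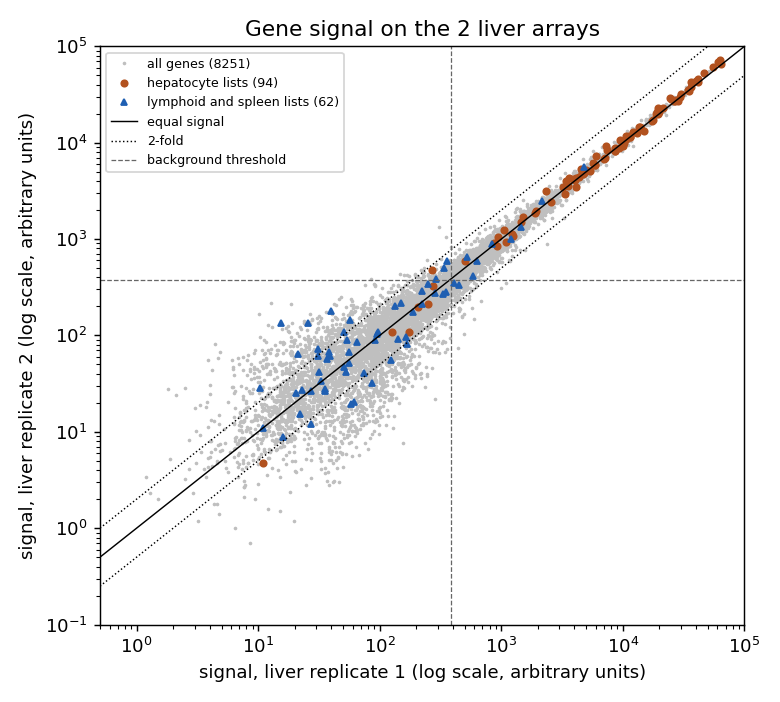
Signal of each of 8251 genes on liver replicate 1 (x axis) against liver replicate 2 (y axis), both on log scales in arbitrary units. Orange circles are the 94 genes of the hepatocyte lists, blue triangles the 62 genes of the lymphoid and spleen lists, dotted lines mark a 2-fold difference and dashed lines the background threshold (386.8 and 373.3); 87 of the orange and 8 of the blue genes lie above it on both arrays.

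The titles and the source field disagree, so gene lists of both tissues were set side by side. Hepatocyte genes filled the bright end of both arrays and lymphocyte and spleen genes did not. The 94 genes of 4 hepatocyte lists (plasma proteins, complement, drug metabolism, urea cycle) had a median percentile of 97.98 on replicate 1 and 98.00 on replicate 2, with median signals of 8653 and 8772. The 62 genes of 3 lymphoid and spleen lists had a median percentile of 24.2 and 30.3, with median signals of 70.1 and 90.8. Above background on both arrays were 87 of the 94 (92.6%) and 8 of the 62 (12.9%). The hepatocyte median exceeded that of all 10000 random lists of the same size, and the lymphoid median exceeded that of 0.01% of them. The 8 lymphoid-list genes above background were Cd74, H2-Aa, H2-Ab1 and H2-Eb1, which encode the invariant chain and class II antigen-presenting molecules also made by macrophages, the immunoglobulin heavy chain gene Ighm, the kinase Zap70, the adaptor Lat and the prostaglandin-degrading enzyme Hpgd. H2-Ab1 was named after its value was seen, to complete that count. Cd79a, a part of the B cell receptor, gave 450.3 on replicate 1 and 333.4 on replicate 2 and so passed the threshold on 1 array. Cd3e, a T cell receptor chain, gave 53.8 ± 3.18. Ighm had 16 probe sets, and its brightest gave 609.7 ± 28.2. No other Ighm set was above background on both arrays, so its place among the 8 rests on that set. The next brightest gave 399.2 on replicate 1 and 284.4 on replicate 2.

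Genes of secreted proteins and intermediary metabolism lay at the bright end of both arrays. All 35 measured plasma protein genes were above background on both arrays, from Apoe down to the clotting factor F7 at 3113 ± 283.2. Of 11 complement genes 10 were above it, led by C8g (12850 ± 395.1) and Cfi (11510 ± 49.4), and the exception was Cfb, factor B, at 141.0 ± 44.5. Of 29 drug metabolism genes 26 were above it, including Cyp2d10 (31281 ± 1475) and Gstm1, a glutathione transferase (27600 ± 64.4), while the epoxygenase Cyp2j5 gave 118.1 ± 11.7. Of 19 genes of the urea cycle and amino acid breakdown 16 were above it, with Tdo2, the first enzyme of tryptophan breakdown, at 34791 ± 715.9 and Cps1, the entry enzyme of the urea cycle, at 27541 ± 851.7. The transaminase gene Got1 was at 7.85 ± 4.45, from a single probe set. The medians of these lists each exceeded all 10000 random lists.

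The gluconeogenesis and glycogen, fatty acid, and bile acid and cholesterol lists had median percentiles of 96.33, 95.02 and 91.07, each above all 10000 random lists. Above background on both arrays were 9 of 10 gluconeogenesis and glycogen genes, 18 of 20 fatty acid genes and 14 of 15 bile acid and cholesterol genes. Examples were the gluconeogenic enzymes Fbp1 (22955 ± 178.0) and Pck1 (9455 ± 803.5), the thiolase Acaa2 (34269 ± 1174), the desaturase Scd1 (21026 ± 2074) and the bile acid carrier Slc10a1 (10459 ± 653.2). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, gave 543.2 ± 32.5, at percentile 71.5. Acadvl, an acyl-CoA dehydrogenase of very long chains, gave 25.6 ± 24.0 and was not above background. All 18 measured acute phase genes were above it. They ranged from Hp and the haem carrier Hpx (37024 ± 1318) to the serum amyloid gene Saa3 (525.7 ± 40.5), with the metallothionein Mt1 at 25216 ± 61.2. Several of these genes also stand in the plasma protein list. The ribosomal protein and oxidative phosphorylation lists had median percentiles of 96.9 and 96.4, above all 10000 random lists. Rps15 at 24.8 ± 25.2 and Cox8a at 23.7 ± 19 were their lowest members.

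**Figure D2:**
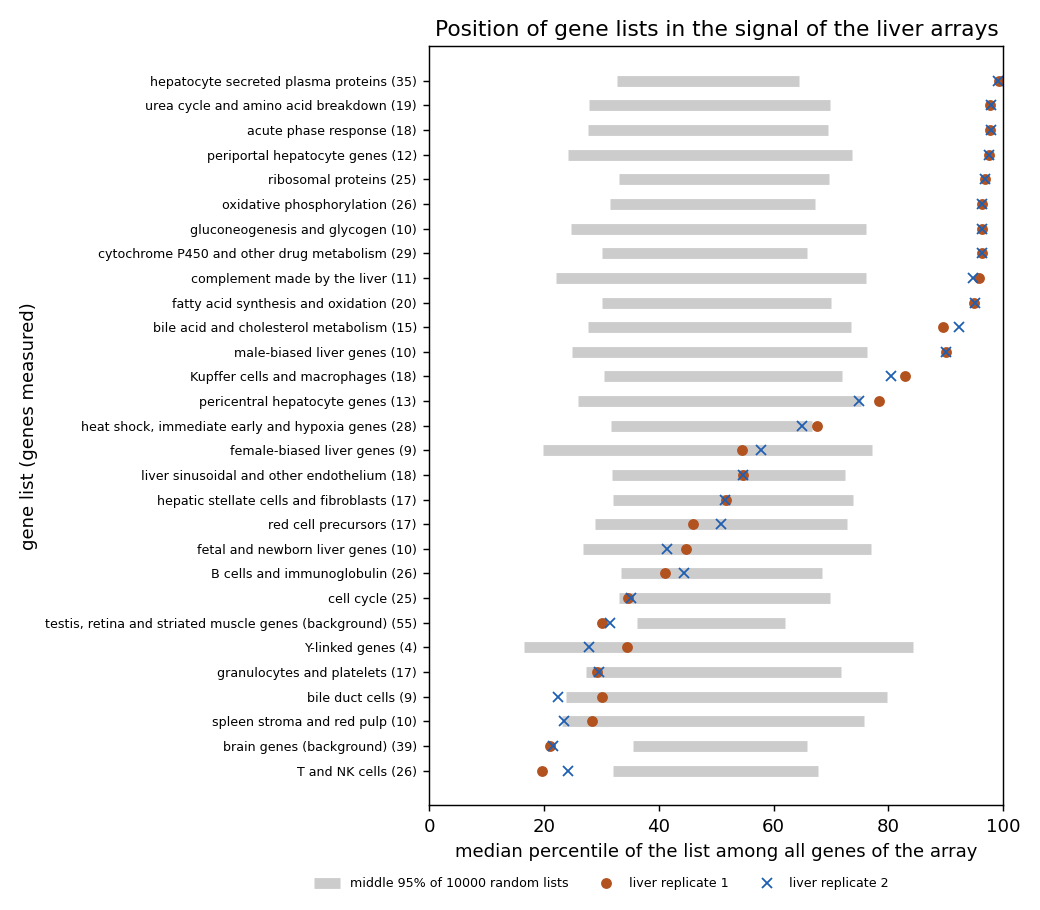
Median percentile of each gene list among all genes of the array (x axis) for liver replicate 1 (circles) and liver replicate 2 (crosses), with the number of measured genes in brackets; grey bars span the middle 95% of 10000 random lists. The plasma protein, complement, drug metabolism and urea cycle lists lie at or above 94.7, and the T and NK cell list lies at 19.7 and 24.1.

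Both zones of the liver lobule were represented. Of 12 genes typical of the periportal zone 10 were above background, with a median percentile of 97.6, and they included Cps1, Igf1 (13171 ± 865.2) and Arg1, arginase (10794 ± 352.6). Of 13 genes typical of the pericentral zone 8 were above it, with a median percentile of 76.6, and they included Cyp2e1, Aldh1a1 (24092 ± 1995) and Cyp1a2 (17520 ± 299.0). The stem cell marker Lgr5 of that list gave 20.8 ± 3.96. The pericentral median exceeded 98.1% of random lists for the mean of both arrays and 97.3% on replicate 2 alone, which lies inside the middle 95%. Sets of probes differ between these lists, and their medians are not a comparison of the zones.

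Genes of the other liver cell types were above background in part. Of 18 Kupffer cell and macrophage genes 12 were above background, with a median percentile of 82.0 that exceeded 99.9% of random lists. Among them were the complement components C1qc (2763 ± 314.8) and C1qa (2464 ± 109.5) and the Kupffer cell lectin Clec4f (2511 ± 146.9), whereas the scavenger receptor Marco gave 21.2 ± 3.39. Also above background were 4 of 18 endothelial, 5 of 17 stellate cell and fibroblast and 1 of 9 bile duct genes. Their brightest members were the endothelial co-receptor Eng (3851 ± 246.6), the proteoglycan Dcn (6806 ± 310.6) and the annexin Anxa4 (995.5 ± 78.2). The medians of these 3 lists lay within the middle 95% of random lists. The bile duct median fell below that range on replicate 2 alone, where it exceeded 1.93% of random lists, and with the mean of a gene's probe sets, where it exceeded 0.12%. The spleen stroma median also fell below it on replicate 2 alone (2.36%).

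Of the genes of blood and lymphoid cells, those above background were 2 of 26 T and NK cell genes, 5 of 26 B cell genes, 2 of 17 granulocyte and platelet genes and 6 of 17 red cell precursor genes, against 34.5% of all genes. The alpha-globin gene Hba-a1 gave 24492 ± 589.4 and Alas2, the erythroid haem synthesis enzyme, 1947 ± 306.7. The granulocyte list was led by Lcn2 (2373 ± 213.5), which hepatocytes also make and which stands in the acute phase list. The T and NK cell median exceeded 0.02% of random lists, and the medians of the other 3 lists lay within the middle 95%. Of 25 cell cycle genes, Tk1, thymidine kinase (1108 ± 31.0), and the replication clamp Pcna (477.5 ± 88.6) were the 2 above background. The other probe set of Tk1 gave 181.7 on replicate 1 and 180.8 on replicate 2. The median of the cell cycle list lay within the middle 95% of random lists, and below it with the mean of a gene's probe sets (0.43%) and without probe sets of suffix f, s, r, i or g (0.19%). Of 10 fetal liver genes, Tpt1, a gene expressed widely in adult cells (26354 ± 592.6), was above background and the fetal albumin homologue Afp was not (125.2 ± 0.778). Of 28 heat shock, immediate early and hypoxia genes 14 were above it, including Jund (5563 ± 708.5) and Hspa8 (5074 ± 330.2). The median of that list exceeded 97.0% of random lists, and it lay above the middle 95% on replicate 1 alone (97.9%) and without the suffixed probe sets (99.3%).

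Genes with known sex bias in mouse liver were measured in part. Of 10 male-biased genes 9 were above background, with Mup3 at 48070 ± 3007 and Mup5 at 35298 ± 3548, and Elovl3, a fatty acid elongase, at 119.2 ± 16.4. Of 9 female-biased genes 3 were above it, namely the sulfotransferase Sult2a2 (4790 ± 9.90), Cyp2b9 (992.2 ± 67.3) and the steroidogenic Cyp17a1 (728.6 ± 238.8). The other probe set of Cyp17a1 gave 10.7 on replicate 1 and 9.2 on replicate 2. Xist, the X-inactivation transcript, gave 421.9 on replicate 1 and 298.1 on replicate 2, above the threshold on 1 array. None of the 4 measured Y-linked genes was above it, and the brightest, Eif2s3y, gave 256.7 ± 5.44. The male-biased median exceeded 99.96% of random lists and the female-biased median 73.6%.

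The second question was how far the 2 arrays differed. Among the brighter 50% of probe sets (6211), log2 signals correlated across probe sets with Pearson's r of 0.975 and Spearman's rho of 0.951, where probe sets are not independent replicates. The SD of the log2 difference was 0.362. A difference of over 2-fold was found in 130 probe sets (2.09%, exact 95% binomial interval 1.75 to 2.48%), of which 62 were higher and 68 lower on replicate 2. The spread fell with signal. When all probe sets were cut into 10 bins of signal, the dimmest bin (median signal 10.9) had an SD of 1.58 with 44.4% over 2-fold, and the brightest bin (median signal 3077) had an SD of 0.175 with 0.161% over 2-fold. With 1 array on each side, no difference has a replicate check.

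**Figure D3:**
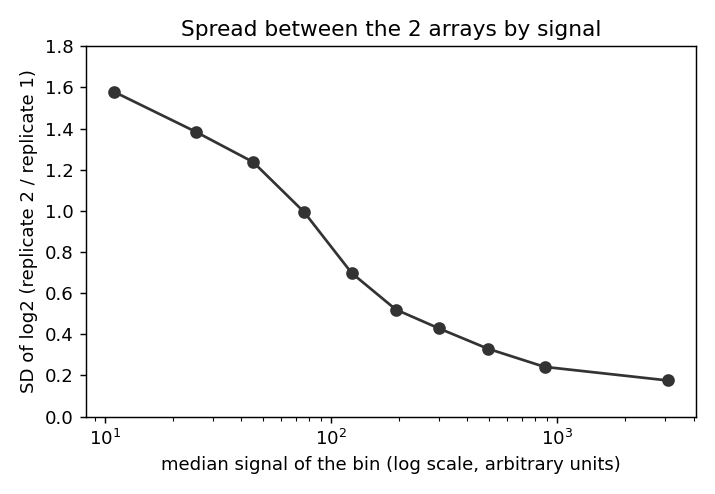
SD of the log2 ratio of replicate 2 to replicate 1 (y axis) in each of 10 signal bins of probe sets against the bin's median signal (x axis, log scale, arbitrary units). The SD falls from 1.58 in the dimmest bin to 0.175 in the brightest.

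The 10 genes named first here are the most different in each direction among the brighter genes, in equal number from both directions. They are not the 10 largest differences, as Tfrc below shows, and do not speak for all large differences. Their mean signals lay between 289.4 and 821.8. All 10 of these genes were not above background on the array with the lower signal, so the size of their differences is uncertain. Signals are given on replicate 1 against replicate 2. Higher on replicate 2 were Tradd, an adaptor of death receptor signalling (304.8 against 1339), Inpp5a (145.9 against 432.9), Hap1 (353.1 against 1045), Myoz1 (157.0 against 428.0) and Pcbp4 (168.3 against 425.3). Lower on replicate 2 were Hat1, a histone acetyltransferase (492.8 against 104.4), Celsr2 (593.0 against 149.3), the translation factor Eif4a1 (997.3 against 307.5), 1110032A03Rik (1103 against 349.6) and Cdh3 (477.7 against 156.1). Tfrc, the transferrin receptor of the red cell list, gave 2382 on replicate 1 and 887.2 on replicate 2 in its brighter probe set and 77.0 and 71.4 in its other one. Its brighter set was above background on both arrays and differed more than that of Pcbp4. The second probe set of Celsr2 gave 179.3 and 176.8, that of Inpp5a 215.5 and 286.6, that of Hat1 66.6 and 47.3 and that of Cdh3 93.2 and 84.1. Tradd, Eif4a1 and 1110032A03Rik were each read from a single probe set of suffix r, and Hat1 from a set of suffix f. Sets of suffix r or i differed over 2-fold more often than plain ones, as given below.

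Gene lists were compared between the arrays with random lists of matched signal. Of the 24 lists with at least 5 genes in the brighter 50%, 4 lay outside the middle 95% of random lists, where 1.2 would by chance. The cell cycle list was higher on replicate 2 by a median log2 of 0.38 (5 of 6 genes) and stayed outside in 5 of 6 alternatives that gave a value, where its median ran from 0.15 (all probe sets) to 0.41. Of those 6 genes, 4 were not above background on both arrays. The B cell list was higher by 0.21 (5 of 9 genes) and stayed outside in 2 of 6, where its median ran from 0.08 (without the suffixed probe sets) to 0.21, with 0.11 for all probe sets; 4 of its 9 genes were not above background on both arrays, against 2 of 14 in the macrophage list and 3 of 17 in the heat shock list. The macrophage list was lower, with a median of -0.16 (5 of 14 genes higher), and stayed outside in 4 of 7, where its median ran from -0.18 to -0.04. The heat shock and immediate early list, at -0.13 (6 of 17 higher), lay on the lower edge of its random range, and was outside in 4 of 7, where its median ran from -0.16 to -0.12. The plasma protein list, with a median of 0.08 and 29 of 35 genes higher on replicate 2, lay within its random range of 0.01 to 0.10. Among the brightest 25% of genes 0 lists lay outside, but the cell cycle and B cell lists had too few genes there to be tested. Without the suffixed probe sets 1 list lay outside. Leaving out the shift moves a list and its random lists alike, so that alternative could not change a call. The counts of alternatives above each include it as outside.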

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

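Probe sets outside the gene lists carried signal. Of 1193 non-control probe sets with no gene name here, 200 (16.8%, exact 95% binomial interval 14.7 to 19%) were above the background threshold on both arrays, against 28.9% of the probe sets that name 1 gene, and 6 of them were among the 125 brightest. The brightest of these reached 33154 on replicate 1 and 34658 on replicate 2. A control probe set of the array for the murine B2 repeat, a short interspersed element, gave 52112.8 ± 2925 (SD, n = 2 arrays). Another control probe set with b2 in its name gave 1611 on replicate 1 and 1924 on replicate 2, so the high signal rests on 1 set.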

How the results depend on the processing

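Agreement between the arrays depended on the signal range. With all probe sets r was 0.937, rho 0.946, the SD 0.901 and 18.2% differed over 2-fold. In the brightest 25% these were 0.986, 0.959, 0.238 and 0.451%. With log2(value + 32), r was 0.978, the SD 0.328 and 1.48% differed over 2-fold. Without probe sets of suffix f, s, r, i or g the SD was 0.335 and 1.44% differed. The lists that differed between the arrays numbered 0 in the brightest 25%, where the cell cycle and B cell lists had too few genes to be tested, and 1 without those suffixes, and 3 or 4 otherwise; of the alternatives that gave a value, the cell cycle list stayed outside in 5 of 6, the macrophage list in 4 of 7, the heat shock list in 4 of 7 and the B cell list in 2 of 6, with no change of direction. Each of these list counts includes the alternative without the shift, which could not change a call. The lists below the random range numbered 5 with the mean of a gene's probe sets and 3 to 5 with 1 array left out. The hepatocyte median percentile was 97.83 with the mean of a gene's probe sets, 98.08 without the suffixes, and 97.98 to 98.00 with 1 array left out. The cause of these changes was not tested. The other 51 alternative values, quantile normalization and the background thresholds among them, stayed within 1.5 times or the spread of the main value. Some of these could not move, because leaving out the shift does not alter r, rho, the SD or which lists lie outside. Of the values of single lists under these alternatives, 221 stayed within their spread and 82 moved beyond it. Of 29 lists, 24 kept their side of the random range under each alternative. No paired analysis was possible because there is 1 group. Dim signals limit what can be said of low genes.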

Other observations

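The tests on the spleen label were chosen after the list positions were seen, and the tests limited to other probe sets above background after the wider test was seen. The other tests in this part were set before their results were seen. The values given next, for the transferrin receptor controls and the 100 brightest probe sets, were not among the planned comparisons. The array's 3 control probe sets for the transferrin receptor, all below the background threshold, gave 158.5, 61.6 and 20.3 on replicate 1 and 86.3, 26.1 and 10.9 on replicate 2. These and both Tfrc probe sets of the main array were lower on replicate 2. The dimmer Tfrc set (77.0 and 71.4) was also below the threshold. Signals this low differ widely between the arrays, so the shared direction does not show a change in the transcript. Among the 100 brightest probe sets, 80 were higher on replicate 2, by a median of 1.05-fold.

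The source field names spleen. If spleen RNA had been hybridised, lymphoid and spleen genes would lie as high as hepatocyte genes. Their median percentile was instead lower by 70.6 points (difference -70.6, 95% bootstrap interval over genes -77.3 to -62.5), which argues against it on both arrays. A small share of spleen RNA in liver RNA stays open: T and NK cell genes differed from the background genes by -5.25 points (interval -13.5 to 4.11), and liver holds lymphocytes of its own, so the 2 cannot be told apart here.

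Of the 130 probe sets that differed over 2-fold between the arrays, 28 had another probe set for the same gene in the brighter 50%. If the samples held different amounts of those transcripts, the other probe sets would differ the same way. Their median log2 difference in that direction was -0.0069 (95% bootstrap interval -0.13 to 0.14), against 1.23 for the differing sets. This test decides nothing alone, although it met its limit, because some of the other sets lay below the background threshold, where a change in the transcript need not show. With other sets above the threshold on both arrays, 17 remained and the median was -0.0013 (interval -0.097 to 0.15), which decides nothing either, because a set that fell below the threshold on 1 array is dropped by that rule. With those above it on at least 1 array, 19 remained and the median was -0.089 (interval -0.14 to 0.12), which argues against different amounts of transcript for these 19 as a set, unless the sets read different transcript forms. Per gene the values ran from -0.48 (Hdgf) to 0.34 (H2-K1), so the median does not speak for each gene. Different amounts of transcript stay open for single genes and for the rest. Probe sets of suffix r or i, built from reduced or mixed probes, differed over 2-fold 3.24 times as often as plain ones at matched signal (interval 1.89 to 5.0), so probe design may account for part of the pattern. They made up 24 of the 130, and 89 were plain sets, for which no source was identified.

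Of 51 ribosomal protein and oxidative phosphorylation genes, 14 were not above background on both arrays, among them Rps15 and Cox8a. The 14 include Cox7a1, named after its value was seen, the isoform of heart and skeletal muscle, for which a low signal in liver is expected; the others are used by most cells. Of the 15 such genes with more than 1 probe set, 7 (46.7%, exact 95% binomial interval 21.3 to 73.4%) had 1 probe set above the threshold and another not above it. A gene is read from its brightest probe set, so none of these 7 is among the 14, and the 6 of the 14 with more than 1 probe set had 0 above the threshold. Whether the probe set or the transcript sets the low signal cannot be told apart here. Whether sets of suffix r or i fail more often stays open: 8 of 12 did, against 22 of 49 plain sets, a difference of 21.8 percentage points (95% bootstrap interval -10.4 to 51.9). For this pattern no biological explanation was tested, because the design names no second condition.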
